A study of Mus musculus with 12 samples.

How the data were processed

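RNA was sequenced from 12 libraries of mouse B cells, 3 for each of 4 groups: marginal zone B cells derived ex vivo (eMZB) and transitional B cells (TrB), with and without LSD1. Per the labels' protocols, RNA from 2000 sorted cells per library was turned into cDNA with the SMART-Seq v4 kit, and libraries were made with the Nextera XT kit, which does not mark strand. The submitters' processing notes name STAR and mm10; the version of STAR, the counting program, the annotation, the gene lengths and the read total behind the values are not given in the sources used here. The authors deposited FPKM per gene and library, reads per kilobase of gene length and per M reads of a library total (M, mega), in 1 table of 9842 genes with Entrez IDs. Every listed gene reached 1 FPKM in at least 3 libraries, so the planned filter on low values removed nothing. Of the IDs, 9833 matched a symbol in the reference gene table and 9 did not; these 9 stayed in the tests. No mitochondrial gene was listed, and 0 value columns were left unused. Positions are those of mm10 (GRCm38) in the RefSeq gene annotation, matched by Entrez ID and counted from 1.

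Whole read counts were recovered from the FPKM values for depth and for checks. For all 9842 genes a length was found at which every value was a whole number of reads within 0.02 reads, together with 1 read total per library; the median length was 3043.5 bases. For 177 of 197 single-exon microRNA and snoRNA genes the recovered length equalled that of the reference. Read totals ran from 7.24 to 19.35 M reads per library and reads in the listed genes from 1.96 to 8.78 M reads. PCR reads without molecular identifiers are not independent molecules, so read numbers bound counting error alone. No pair of replicates was a duplicate: differences between replicates exceeded counting noise by 2.59 to 17.7 times.

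The planned fit, written with the gene lists, the rule for named genes and the alternatives before the data were examined, was limma (3.58.1, R 4.3.3) on log2 of the deposited FPKM plus 1. All 12 libraries entered a fit of 4 group means with 8 residual degrees of freedom, using lmFit and eBayes with trend, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no fold threshold. The contrasts were TrB_KO against TrB_WT, eMZB_KO against eMZB_WT, eMZB_WT against TrB_WT, eMZB_KO against TrB_KO, and the interaction, the eMZB response to LSD1 loss minus the TrB response. The same fit on FPKM divided by median-of-ratios factors (0.613 to 2.14, computed over genes above 0 in all libraries) was among the alternatives. It was made the lead after the data were seen, because the deposited scale differed between libraries; every alternative was then run on both scales. Overlap of calls was tested with Fisher's exact test, two-sided, per direction. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for read recovery, other checks and figures.

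Of 28 gene lists, 22 had at least 3 tested members and were tested with camera in limma, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a contrast. They were B cell identity, transitional and immature B cell, marginal zone B cell, follicular B cell, plasma cell, Notch pathway, NF-kB pathway, LSD1 complex, cell cycle, MYC and ribosome biogenesis, oxidative phosphorylation, glycolysis, unfolded protein response, interferon response, p53 targets, migration and adhesion, activation and immediate early, Toll-like receptor, MHC class II, heat shock, macrophage and monocyte markers, and stromal cell markers. Lists of markers of T cells, neutrophils, dendritic cells, NK cells, erythroid cells and platelets had fewer than 3 tested members and gave no test. Members were counted over all genes and adjusted over the list alone. Some genes stand in more than 1 list, such as Itgb7 (follicular; migration and adhesion) and Dtx1 (marginal zone; Notch pathway).

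Named genes followed a rule. It took Kdm1a and the sorting markers in every group. For both LSD1-loss contrasts and the wild-type cell type contrast it took the 10 largest rises and 10 largest falls among called genes with a group mean of at least 5 FPKM and no overlap between libraries, without predicted genes or immunoglobulin segments. For the interaction it took 5 in each direction, and for each list up to 4 members with the smallest adjusted p. The rule was applied to deposited values and, as a choice made after the data were seen, to scaled values. Not every gene it took is named in the text. Genes it does not cover, the shared genes and those of the knockout cell type contrast among them, were taken from the overlap or followed from wild type.

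Labels number the replicates 1 to 3 in each group without saying what a number shares. Deviations from group means were correlated between libraries of the same number. In the pair TrB_KO and eMZB_KO every correlation was over 0.1: 0.239, 0.246 and 0.445 as deposited and 0.161, 0.106 and 0.292 after scaling. By the rule set beforehand, numbers therefore paired the knockout libraries across cell types, on the evidence of the data alone, and no other pair of groups. Single correlations elsewhere reached 0.286 as deposited (TrB_KO and eMZB_WT, number 2) and 0.273 after scaling (TrB_WT and eMZB_WT, number 3). The pairing was not tested against chance. A replicate block changed the knockout cell type counts by under 1.5 times.

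Alternatives covered the pseudocount (0.1 and 5), a filter at 5 FPKM, median-of-ratios, quantile and TPM scaling, eBayes without trend and with robust fitting, library weights, fits on the compared groups alone, replicate blocks, a log2 fold threshold of 1, an estimated correlation for camera, and each library left out in turn. Added after seeing the data were the alternatives on the scaled base, the block in knockout libraries alone, fits without the libraries numbered 3, fits without microRNA and snoRNA genes, and voom on recovered reads. The fit was tested on simulated libraries of 9842 genes in which 200 genes changed by a log2 of 1 or 2. At a log2 of 1 it recovered 46% of the changed genes in TrB as deposited and 95% after scaling, in eMZB 2% and 90%, and between the wild-type cell types 50% and 96%. At a log2 of 2 it recovered 79% and 99%, 99% and 99%, and 61% and 99%. Unchanged genes called numbered 44, 18 and 72 as deposited and 15, 14 and 16 after scaling. Values were drawn from group means and spreads of the scaled fit, and the deposited version multiplied them by the scale factors. Changed genes rose and fell in equal number. Scaling was therefore favoured by construction, and these shares cannot show which scale is better for the real libraries. In a simulation of 20 lists, 1 of them raised, camera called the raised list and 0 of the unchanged lists. Noise was drawn independently for each gene. This simulation therefore cannot show how often camera calls unchanged lists of correlated genes.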

Results

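The series measured messenger RNA in B cells of female C57BL/6J mice with and without LSD1, the histone demethylase encoded by Kdm1a. Splenic transitional B cells (TrB) were sorted, without stimulation, as cells positive for B220 and CD93 and negative for Thy1.1, F4/80 and CD11b. Ex vivo-derived marginal zone B cells (eMZB) came from transitional B cells cultured for 3 days with the survival factor BAFF and the Notch ligand DL1, and were sorted with the same exclusions as cells positive for B220, CD1d and CD21. The 12 libraries, each from 2000 cells, fell into 4 groups of 3: TrB_WT, TrB_KO, eMZB_WT and eMZB_KO. The labels do not say whether the 3 replicates of a group came from separate animals, so each test measures the spread between these libraries, which may be technical. Values are means ± SD of FPKM after median-of-ratios scaling, n = 3 libraries per group, unless stated otherwise. Log2 changes carry the standard error (SE) of the limma fit. Each gene named as rising or falling had an adjusted p under 0.05 in limma and no overlap between the libraries of both groups, an arrangement that chance gives in 10% of unchanged genes. Counts of list members that rose or fell, and of genes shared by contrasts, rest on adjusted p and sign alone, without the condition on overlap.

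The deposited table listed 9842 genes. Read totals behind the FPKM values ranged from 7.24 M reads (eMZB_WT replicate 2) to 19.35 M (eMZB_WT replicate 3), and reads in the listed genes from 1.96 M (TrB_WT replicate 3) to 8.78 M (TrB_KO replicate 3). The listed genes held 16.7%, 20.1% and 16.9% of the reads in the TrB_WT libraries. In TrB_KO these shares were 17.2%, 20.9% and 61.6%. They were 34.5%, 27.8% and 35.3% in eMZB_WT and 30.9%, 29.0% and 41.7% in eMZB_KO. TrB_KO replicate 3 stood apart from the other transitional libraries in this share and in having 285 listed genes at 0, against 30 to 52 in the others. A principal component with 50.9% of the variance separated the cell types, and the next, with 16%, separated TrB_KO replicate 3 from the other 11 libraries. Replicates correlated across genes with Pearson r of 0.946 to 0.971 in TrB_WT, 0.926 to 0.971 in TrB_KO, 0.975 to 0.982 in eMZB_WT and 0.982 to 0.986 in eMZB_KO.

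Kdm1a (Entrez 99982, chromosome 4, 136550533 to 136602787, mm10) was lower in the knockout libraries, and 1 library labelled wild type in each cell type lay near them. In TrB_KO its scaled FPKM was 3.35, 2.56 and 2.99, against 8.54 and 7.93 in TrB_WT replicates 1 and 2 and 3.47 in the library labelled TrB_WT replicate 3. In eMZB_KO it was 2.65, 2.53 and 2.66, against 7.53 and 8.63 in eMZB_WT replicates 1 and 2 and 4.68 in the library labelled eMZB_WT replicate 3. The log2 change was -0.87 (SE 0.26, adjusted p = 0.249) in TrB and -1.10 (SE 0.26, adjusted p = 0.148) in eMZB, neither past the threshold. Gene-level values do not show which exons the remaining Kdm1a reads came from. Both libraries with low Kdm1a stayed in the comparisons under their labels, and each direction below draws on them. The 11 tested genes of the LSD1 complex list, among them Rcor1 and Hdac1, held 0 called genes with LSD1 loss by limma, also when adjusted over the list alone, and camera gave adjusted p = 0.45 in TrB and 0.959 in eMZB. Among the sorting marker genes, Ptprc (CD45, the gene of B220) had 51.5 ± 6.69 in TrB_WT and 56.5 ± 5.88 in TrB_KO. Cd93 had 5.002 ± 0.780 and 5.22 ± 0.782 in the same groups, and 0.873 ± 0.203 in eMZB_WT and 0.831 ± 0.158 in eMZB_KO. Cd1d1 had 22.8 ± 0.241 in eMZB_WT and 27.8 ± 2.90 in eMZB_KO. Adgre1 (F4/80) had 2.27 ± 0.196 in TrB_WT, 1.31 ± 0.320 in TrB_KO, 0.661 ± 0.193 in eMZB_WT and 0.787 ± 0.233 in eMZB_KO. Thy1 was not analysed here, since it was not among the listed genes.

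**Figure D1:**
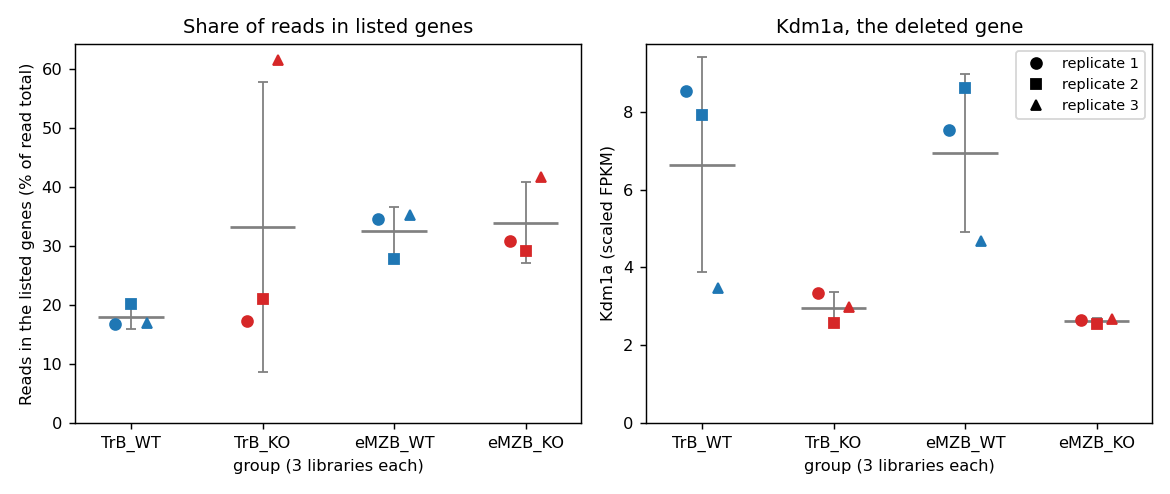
Left, the percent of reads in the listed genes, and right, Kdm1a in scaled FPKM, for each of the 12 libraries; grey bars give the mean and SD of 3 libraries. TrB_KO replicate 3 lies at 61.6% of reads, and the libraries labelled WT replicate 3 hold 3.47 (TrB) and 4.68 (eMZB) Kdm1a.

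The deposited scale differed between libraries, with FPKM sums over the listed genes from 60647 to 212404, and the median gene moved with it. As deposited, the median log2 change of all genes was 0.52 for LSD1 loss in TrB, 0.06 for LSD1 loss in eMZB, 0.67 between the cell types in wild type, 0.23 between them in knockout and -0.46 for the interaction. The planned fit on deposited values called 19, 15, 1896, 460 and 15 genes in these contrasts, and leaving out 1 library moved those counts over wide ranges. They ran from 17 without TrB_KO replicate 3 to 195 without TrB_KO replicate 1, from 13 without eMZB_KO replicate 3 to 42 without TrB_KO replicate 3, and from 614 without eMZB_WT replicate 1 to 7459 without TrB_KO replicate 3. For the knockout cell type contrast they ran from 191 without eMZB_KO replicate 3 to 6688 without TrB_KO replicate 3, and for the interaction from 4 without TrB_KO replicate 3 to 46 without TrB_KO replicate 1. The comparisons below therefore lead with the median-of-ratios scaling, which was on the list of alternative scalings beforehand and was made the lead after the data were seen, and give the deposited counts beside it. MicroRNA and snoRNA genes, with a median of 2 reads per library, made up 12 of the 19 genes called as deposited in TrB, 6 of the 15 in eMZB and 12 of the 15 in the interaction. After scaling they made up 6, 0 and 0 of the calls.

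Transitional B cells without LSD1 were compared with wild-type transitional B cells, which asks what the demethylase does before the cells enter culture. Ly6c2 (Entrez 100041546), a surface protein of monocytes and of activated lymphocytes, rose from 7.80 ± 1.75 to 51.7 ± 7.30, a log2 change of 2.59 (SE 0.22). Its reads cannot be told from those of the near-identical Ly6c1. Ly6a (Entrez 110454), the surface antigen Sca-1, rose from 27.7 ± 7.95 to 77.4 ± 5.37. Itgb7 (Entrez 16421), an integrin chain used in homing to the gut, rose from 5.50 ± 0.248 to 13.2 ± 2.53. Ctse (Entrez 13034), the protease cathepsin E, rose from 13.5 ± 0.868 to 27.9 ± 2.28.

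Further genes that rose in TrB_KO were Ddx23 (Entrez 74351), an RNA helicase of the spliceosome, with a log2 change of 1.67 (SE 0.15), Slc66a2 with 1.64 (SE 0.12) and Gimap4, a lymphocyte GTPase, with 1.05 (SE 0.12). Rapgef3, the cAMP-activated exchange factor Epac1, rose by 1.40 (SE 0.12); the kit does not mark strand, so its reads cannot be told from those of the antisense gene Rapgef3os2. Srp54a, a subunit of the signal recognition particle, rose by 1.03 (SE 0.10), with reads that may be shared with its copies Srp54b and Srp54c. The microRNA gene Mir1949 rose from 1.72 ± 0.268 to 5.44 ± 0.265, but on a mean of 6.33 reads per library in the higher group. At so few reads the SD does not measure its precision. Genes that fell in TrB_KO included the collagen gene Col5a3, at -1.07 (SE 0.15), Rgs18, a regulator of G protein signalling, at -1.01 (SE 0.14), and Ide, the insulin-degrading enzyme, at -0.94 (SE 0.09). Btg2, an inhibitor of proliferation, fell at -0.46 (SE 0.09, adjusted p = 0.0398) after scaling and had the opposite sign as deposited, 0.16 (adjusted p = 0.763). Of the genes named so far Ly6c2, Ly6a, Ddx23, Slc66a2, Rapgef3 and Mir1949 also passed as deposited, and the others did not. Snord64 was named by the deposited values, at -1.87 (adjusted p = 0.012), and did not pass after scaling, at -2.22 (adjusted p = 0.263).

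By camera, 3 of 22 gene lists rose in TrB_KO. Of 20 tested migration and adhesion genes, 2 rose (Itgb7 among them) and 18 were not called; adjusted over the list alone 6 were higher. The list had adjusted p = 0.00166, and adjusted p = 0.496 with an estimated correlation. Cxcr4, the receptor of the chemokine CXCL12, had 10.7 ± 1.41 in TrB_WT and 17.9 ± 3.62 in TrB_KO (adjusted p = 0.0763). Of 28 NF-kB pathway genes 0 were called over all genes and 4 were higher when adjusted over the list alone, with a list adjusted p = 0.0149, and adjusted p = 0.323 with an estimated correlation. Icam1 had 5.40 ± 0.423 in TrB_WT and 7.67 ± 0.0717 in TrB_KO, and Birc3, an inhibitor of apoptosis, 24.9 ± 2.24 and 31.3 ± 1.92. None of the 10 plasma cell genes was called by limma, 0 when adjusted over the list alone, while the list had adjusted p = 0.0374, and adjusted p = 0.323 with an estimated correlation. Jchain, which joins IgM and IgA polymers, varied between replicates, at 15.5 ± 13.1 in TrB_WT and 39.7 ± 20.7 in TrB_KO (adjusted p = 0.502), and Xbp1, a factor of the secretory programme, had 16.7 ± 2.35 and 21.0 ± 2.93. In lists that did not pass as a whole, single members rose. They were Cd36 and Cr2 (CD21) of 15 marginal zone genes (list adjusted p = 0.121), Myc of 19 MYC and ribosome biogenesis genes (0.0807), and the replication helicase gene Mcm6 of 26 cell cycle genes (0.128). Interferon response genes gave adjusted p = 0.101, Toll-like receptor genes 0.0711, activation genes 0.124, and the 4 tested macrophage and monocyte markers, where Ly6c2 was the called one, 0.32. On deposited values the lowest adjusted p of a list in TrB was 0.101.

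In limma, 49 of 9842 genes passed in TrB after scaling, 38 higher and 11 lower, against 19 as deposited, 11 higher and 8 lower, with 13 in both. Without TrB_WT replicate 1 the scaled count was 26, without eMZB_KO replicate 1 it was 31, without TrB_KO replicate 3 it was 33 and without the library labelled TrB_WT replicate 3 it was 54. Btg2, Cd36, Cr2, Mcm6 and Myc held their call in 2 of the 12 fits that left out 1 library, and the other named genes that passed held theirs in 12. Fits on the TrB libraries alone called 9 genes and voom on recovered reads 21.

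The same comparison in cells that had been cultured to the marginal zone phenotype was eMZB_KO against eMZB_WT. Alox5ap (Entrez 11690), the activating protein of leukotriene synthesis, rose from 0.286 ± 0.0570 to 4.76 ± 0.615, a log2 change of 2.16 (SE 0.19). Flt3 (Entrez 14255), a receptor tyrosine kinase of progenitors and dendritic cells, rose from 0.824 ± 0.207 to 5.15 ± 0.586. Ly6c2 rose from 15.8 ± 5.58 to 49.1 ± 4.60, again with Ly6c1 not separable. Car2 (Entrez 12349), a carbonic anhydrase, rose from 0.897 ± 0.0843 to 5.48 ± 0.530, and Cdh17 (Entrez 12557), a cadherin, from 3.73 ± 0.220 to 11.6 ± 1.13. Ifi208 (Entrez 100033459), a member of an interferon-inducible family whose copies may share reads, had 6.14 ± 0.837 in eMZB_WT and fell to 0.958 ± 0.104.

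Ddx23 rose in eMZB_KO by 1.83 (SE 0.15) on the log2 scale, Ctse by 1.06 (SE 0.09) and Itgb7 by 0.92 (SE 0.11). Erdr1 rose from 21.7 ± 2.98 to 52.9 ± 3.03, the transcriptional repressor gene Zbtb32 by 1.15 on the log2 scale (SE 0.15) and Scimp, an adaptor of MHC class II signalling, by 0.90 (SE 0.15). Genes that fell were Cd55, which protects cells from complement, at -0.83 (SE 0.13), Rnpep, an aminopeptidase, at -0.86 (SE 0.15), Arf3, a GTPase of vesicle traffic, at -0.79 (SE 0.14), Ide at -0.69 (SE 0.09), Btg2 at -0.69 (SE 0.09) and Pnrc2 at -0.64 (SE 0.11). Each of these directions was the same as deposited, but of the genes named for eMZB so far Alox5ap, Flt3, Car2, Ifi208 and Ddx23 passed there, and the others did not (Zbtb32, adjusted p = 0.088; Erdr1, adjusted p = 0.915).

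By camera, 9 of 22 lists were called in eMZB, and 3 of them held with an estimated correlation: MHC class II, MYC and ribosome biogenesis, and macrophage and monocyte markers. MHC class II genes, which present antigen to helper T cells, fell as a list (adjusted p = 2.2e-11; adjusted p = 0.0188 with an estimated correlation), although limma called 0 of 10 over all genes and 6, all lower, when adjusted over the list alone. H2-Aa had 538 ± 58.5 in eMZB_WT and 418 ± 14.4 in eMZB_KO, H2-Ab1 754 ± 94.3 and 571 ± 2.34, and H2-Ob 68.7 ± 1.93 and 54.5 ± 3.15. MYC and ribosome biogenesis genes rose as a list (adjusted p = 7.4e-09; 0.00332 with an estimated correlation), with 0 of 19 called over all genes and 1 higher when adjusted over the list alone. Myc itself had 16.5 ± 1.15 in eMZB_WT and 23.7 ± 2.51 in eMZB_KO (adjusted p = 0.0617), and Ddx21, a helicase of ribosomal RNA synthesis, 5.58 ± 0.633 and 7.55 ± 0.494. The 4 tested macrophage and monocyte markers rose as a list (adjusted p = 8.8e-06; 0.0126 with an estimated correlation), with 1 called over all genes (Ly6c2) and 2 when adjusted over the list alone. Itgam (CD11b) had 0.279 ± 0.0980 in eMZB_WT and 1.14 ± 0.135 in eMZB_KO (adjusted p = 0.0793), Cd68 had 2.03 ± 0.375 and 2.75 ± 0.718, and the sort excluded CD11b+ and F4/80+ cells. All 4 markers were also detected in the transitional libraries of both genotypes.

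The other 6 lists were called in eMZB with the preset correlation alone. B cell identity genes fell (adjusted p = 0.00183; adjusted p = 0.266 with an estimated correlation) with 0 of 16 members called, also over the list alone; Cd79a, a chain of the B cell receptor complex, had 459.7 ± 41.4 in eMZB_WT and 392 ± 9.003 in eMZB_KO. Plasma cell genes fell (adjusted p = 0.00187; adjusted p = 0.105 with an estimated correlation) with 0 of 10 called, also over the list alone. Prdm1, the plasma cell regulator Blimp-1, had 1.57 ± 0.188 in eMZB_WT and 0.890 ± 0.0816 in eMZB_KO, and Jchain 12.1 ± 2.73 and 3.40 ± 2.42. Glycolysis genes rose (adjusted p = 7.6e-04; adjusted p = 0.195 with an estimated correlation) with 0 of 15 called, also over the list alone; Gapdh had 86.4 ± 2.28 and 102 ± 4.11. Migration and adhesion genes rose (adjusted p = 9.6e-04; adjusted p = 0.268 with an estimated correlation), with 1 of 20 called (Itgb7) and 3 over the list alone. Heat shock genes rose (adjusted p = 0.0223; adjusted p = 0.195 with an estimated correlation), with 0 of 7 called and 1 over the list alone; the chaperonin gene Hspd1 had 23.3 ± 1.55 and 28.8 ± 0.210. Cell cycle genes rose (adjusted p = 0.0429; adjusted p = 0.464 with an estimated correlation) with 0 of 26 called, also over the list alone; Tyms, of thymidylate synthesis, had 1.95 ± 0.117 and 2.99 ± 0.335. As deposited, 5 lists were called: plasma cell, MYC and ribosome biogenesis, MHC class II, macrophage and monocyte markers, and stromal cell markers, which fell as deposited (adjusted p = 0.00409) and not after scaling (0.229); without the library labelled eMZB_WT replicate 3 that list turned upward as deposited (adjusted p = 0.0145). None of these 5 held as deposited with an estimated correlation: adjusted p = 0.125 for macrophage and monocyte markers, 0.753 for stromal cell markers and 0.9996 for the other 3. Marginal zone genes gave adjusted p = 0.229; Cr2 had 65.5 ± 4.90 in eMZB_WT and 64.4 ± 1.32 in eMZB_KO.

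In limma, 40 of 9842 genes passed in eMZB after scaling, 33 higher and 7 lower, against 15 as deposited, 11 higher and 4 lower, with 8 in both. The scaled count was 16 without eMZB_KO replicate 1, 19 without eMZB_KO replicate 2, 16 without eMZB_KO replicate 3, 20 without eMZB_WT replicate 1, 21 without eMZB_WT replicate 2 and 16 without the library labelled eMZB_WT replicate 3. Arf3 and Pnrc2 held their call in 6 of the 12 fits that left out 1 library, Erdr1, Rnpep and Scimp in 7, Cd55 in 8, and the other named genes that passed in 12.

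**Figure D2:**
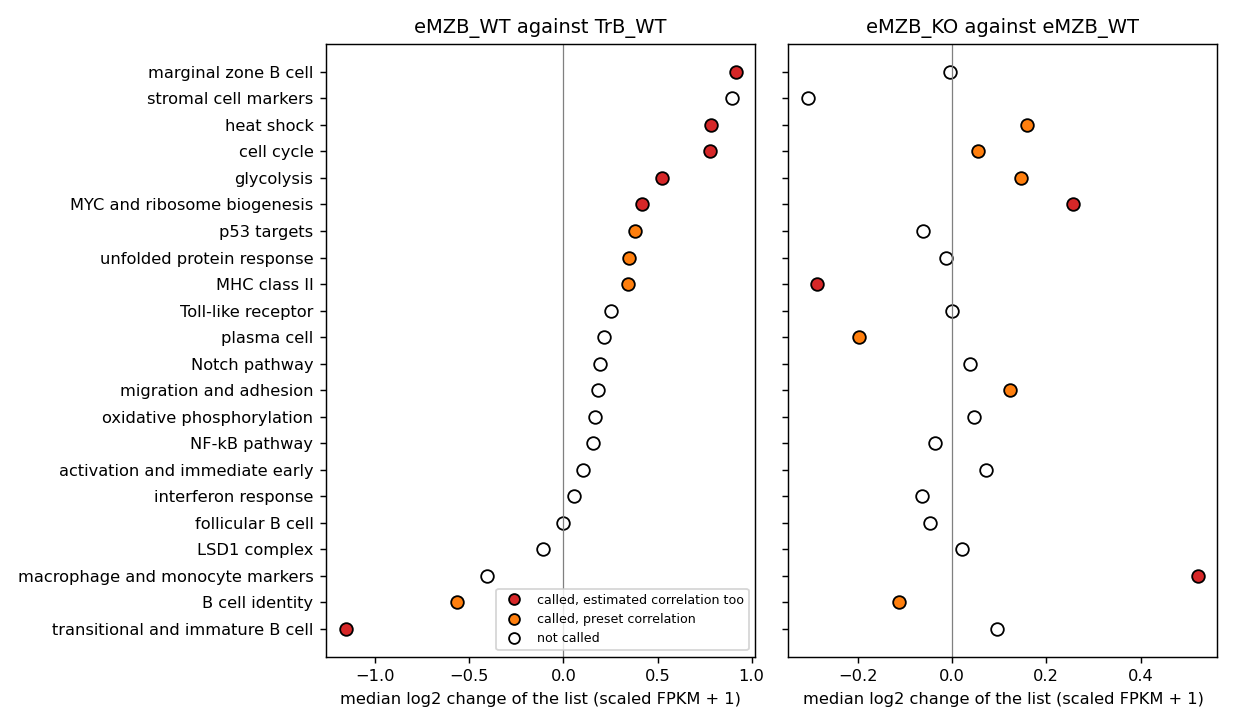
Median log2 change of the tested members of each of 22 gene lists, after scaling, for eMZB_WT against TrB_WT (left) and eMZB_KO against eMZB_WT (right); fill gives the camera call. With LSD1 loss in eMZB the MHC class II list lay lowest among the called lists at -0.29 and macrophage and monocyte markers highest at 0.52; the B cell identity list on the left, -0.57, had a median of 0.30 as deposited.

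The LSD1-loss genes of both cell types, from contrasts that shared no library, were compared gene by gene. Their replicate numbers paired the knockout libraries across cell types in the values. Both contrasts also used the same estimate of spread per gene, from the fit of all 12 libraries. The contrasts were therefore not shown to be independent, as the expected numbers and Fisher's exact test here take them to be. Shared rising genes numbered 14, against 0.127 expected for independent lists (Fisher's exact test, two-sided, p = 8.3e-27), and shared falling genes 3, against 0.00782 (p = 3.6e-08). The 14 were Alox5ap, Csrp1, Ctse, Ddx23, Eno1b, Fam177a, Itgb7, Ly6c2, Ptprv, Rapgef3, Slc66a2, Srp54a, Srp54b and St8sia6, and the 3 were Btg2, Ide and Ifi208. Fam177a has the near-identical copy Fam177a2, so its reads are uncertain as well. Of the 49 genes called in TrB, 38 had the same sign in eMZB, and of the 40 called in eMZB, 36 had the same sign in TrB. Across all 9842 genes, which are not independent replicates, the log2 changes correlated with Pearson r = 0.141 and Spearman rho = 0.0788. As deposited, 2 rising genes were shared (Alox5ap and Ddx23, Fisher's exact p = 6.2e-05) and 0 falling genes (Fisher's exact p = 1). The scaled overlap of 17 was 11 without eMZB_KO replicate 1, 11 without eMZB_KO replicate 2, 10 without eMZB_KO replicate 3, 11 without eMZB_WT replicate 1 and 11 without the library labelled eMZB_WT replicate 3.

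**Figure D3:**
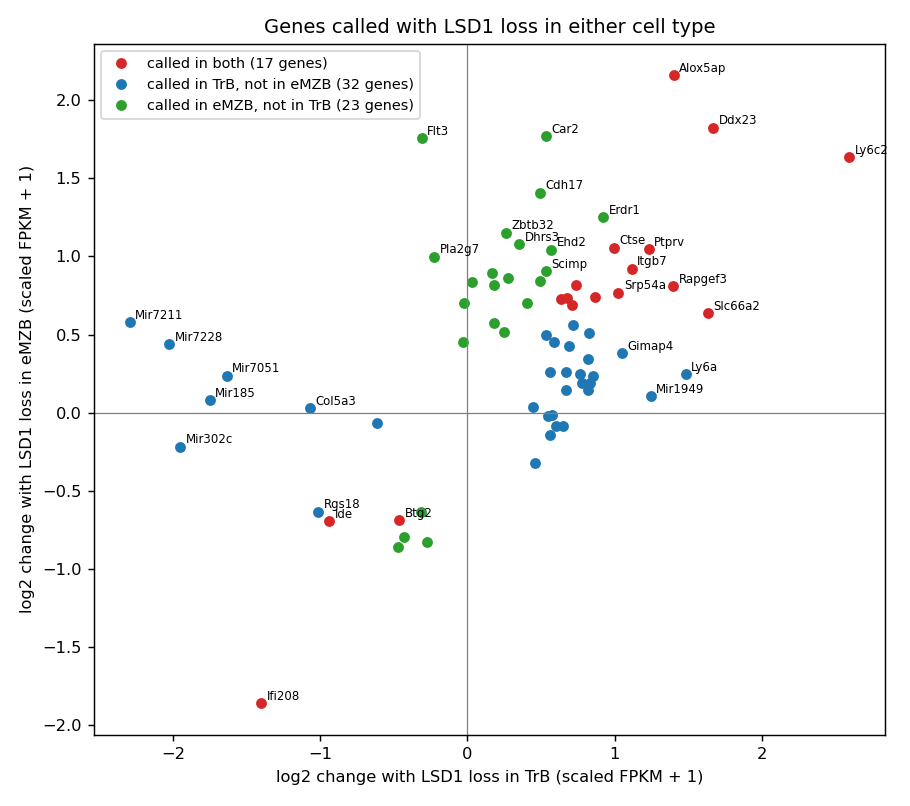
Log2 change with LSD1 loss in TrB (horizontal) and eMZB (vertical), scaled FPKM + 1, for the genes called in either cell type; each point is a gene. The 17 genes called in both share a sign; Btg2 in TrB has the opposite sign as deposited (0.16).

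Whether LSD1 loss acted differently in the cell types was tested by the interaction. Flt3 was the gene that passed after scaling: its response was larger in eMZB by 2.06 (SE 0.19, adjusted p = 9.1e-04), with 0.777 ± 0.0764 in TrB_WT and 0.433 ± 0.0339 in TrB_KO. As deposited the Flt3 interaction was 1.94. Jchain passed as deposited, at -4.17 (adjusted p = 0.00613), and not after scaling, at -3.73 (SE 1.28, adjusted p = 0.686). By camera, 5 lists responded more negatively in eMZB than in TrB, none of which held with an estimated correlation. MHC class II genes had adjusted p = 3.0e-06, and adjusted p = 0.142 with an estimated correlation; plasma cell genes had 8.2e-05, and adjusted p = 0.112 with an estimated correlation. Follicular B cell genes had 0.00665, and adjusted p = 0.285 with an estimated correlation. NF-kB pathway genes had 0.00933, and adjusted p = 0.142 with an estimated correlation, and unfolded protein response genes 0.0372, and adjusted p = 0.691 with an estimated correlation. None of the members of these lists was called by limma over all genes after scaling; adjusted over the list alone, 4 of 10 MHC class II genes and 3 of 10 follicular genes were lower. Limma called 1 gene after scaling and 15 as deposited, 11 higher and 4 lower, with Flt3 in both. The scaled count was 5 without the library labelled TrB_WT replicate 3, 2 without eMZB_KO replicate 1 and 2 without eMZB_KO replicate 2, and Flt3 was called in all 12 such fits. Apart from Flt3, genes called in one cell type and not in the other were not shown to differ between them.

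Wild-type eMZB cells were compared with wild-type transitional cells, a contrast that joins culture with BAFF and DL1 and the different sorting gates. Marginal zone genes rose: of 15 tested, 11 rose, 0 fell and 4 were not called (12 higher when adjusted over the list alone). Cr2 (Entrez 12902), the complement receptor CD21 used in the sort, rose from 8.77 ± 1.14 to 65.5 ± 4.90, Fcrl5 (Entrez 329693), an inhibitory Fc receptor-like protein, from 2.86 ± 0.939 to 27.1 ± 1.22, and the Notch target Dtx1 (Entrez 14357) from 4.70 ± 1.94 to 37.0 ± 2.57. Transitional and immature B cell genes fell: 8 of 9, over all genes and over the list alone, with the surrogate light chain partner Vpreb3 from 251 ± 27.8 to 65.8 ± 6.66, the sorting marker Cd93 from 5.002 ± 0.780 to 0.873 ± 0.203 and the recombinase gene Rag1 from 1.84 ± 0.309 to 0.126 ± 0.0843. Cd1d1, the gene of the other sorting marker, had 22.3 ± 2.52 and 22.8 ± 0.241 (adjusted p = 0.796).

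The largest rises in wild type, on the log2 scale, included Il9r, the interleukin 9 receptor, at 3.52 (SE 0.16), Slc7a5, an amino acid transporter, at 3.38 (SE 0.26), Ly6a at 3.33 (SE 0.17), Plaur, the urokinase receptor, at 3.21 (SE 0.20) and Ccr6, a chemokine receptor, at 2.73 (SE 0.16). Mthfd2, of mitochondrial folate metabolism, rose by 2.50 (SE 0.17) and Apoe, the lipid carrier, by 3.01 (SE 0.31). Cxcl12, a chemokine of stromal cells, rose by 2.55 with uneven libraries, 0.226 ± 0.0646 in TrB_WT and 8.04 ± 6.73 in eMZB_WT. Whether its reads came from the B cells was not tested. Falls included Wfdc21 at -4.82 (SE 0.28), Myadm at -3.58 (SE 0.15), Col5a3 at -3.54 (SE 0.15), Serinc5 at -2.88 (SE 0.10) and Rgs2 at -2.81 (SE 0.12). Atp1b1, a sodium pump subunit, fell at -2.76 (SE 0.19), Pafah1b3 at -2.50 (SE 0.12), Niban3 at -2.40 (SE 0.13) and Smim24 at -2.26 (SE 0.20). All of these kept their sign as deposited.

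By camera, 10 of 22 lists were called in wild type, and 6 held with an estimated correlation. Among these 6, the marginal zone list had adjusted p = 3.1e-10 and the transitional list 1.0e-07. Of 26 cell cycle genes 23 rose (23 over the list alone; list adjusted p = 9.1e-11), with the cyclin gene Ccna2 from 1.93 ± 0.761 to 8.26 ± 1.18 and Rrm2, of nucleotide synthesis, from 4.69 ± 1.01 to 15.6 ± 0.928. Of 19 MYC and ribosome biogenesis genes 12 rose (13 over the list alone; list adjusted p = 8.1e-07), with Myc from 5.72 ± 0.514 to 16.5 ± 1.15 and Npm1 from 29.7 ± 2.50 to 59.5 ± 1.55. Of 15 glycolysis genes 11 rose (11 over the list alone; list adjusted p = 6.1e-08), among them Aldoa and Ldha, and of 7 heat shock genes 5 rose (6 over the list alone; list adjusted p = 3.4e-05), with Hspa8 from 41.1 ± 3.90 to 102 ± 3.19. With the preset correlation alone, unfolded protein response genes rose (8 of 17, 11 over the list alone; adjusted p = 5.5e-05, and adjusted p = 0.219 with an estimated correlation), with the chaperone gene Pdia4 from 31.3 ± 5.53 to 119 ± 10.02. MHC class II genes rose (6 of 10, 6 over the list alone; adjusted p = 0.00193, and adjusted p = 0.219 with an estimated correlation), with H2-Aa from 277 ± 24.4 to 538 ± 58.5. Targets of p53 rose (3 of 8, 5 over the list alone; adjusted p = 0.0365, and adjusted p = 0.219 with an estimated correlation), among them Sesn2 and Bbc3. B cell identity genes fell after scaling (10 lower and 4 higher of 16, 10 and 4 over the list alone; adjusted p = 0.00154, and adjusted p = 0.219 with an estimated correlation). Among them Spib fell from 230.1 ± 20.9 to 88.0 ± 5.98 and Cd79b from 810.0 ± 55.5 to 421 ± 25.8. Cd37 fell after scaling, at -0.72, and had the opposite sign as deposited, 0.15, where the B identity median was 0.30 and the list had adjusted p = 0.128.

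Some lists that did not pass in wild type after scaling held called members in both directions. NF-kB pathway genes had 9 higher and 4 lower of 28 (13 and 6 over the list alone; adjusted p = 0.13), with Traf1 and Bcl2a1b among those that rose; as deposited the list rose (adjusted p = 0.0272, and adjusted p = 0.871 with an estimated correlation). Follicular genes had 4 higher and 4 lower of 10 (adjusted p = 0.982), and their median and mean lay below 0 where the test statistic lay above it. Notch pathway genes had 4 higher and 1 lower of 12 (adjusted p = 0.13), activation genes 5 and 4 of 13 (0.407) and interferon response genes 4 and 2 of 22 (0.618). Toll-like receptor genes, with Tlr7 at 1.43 among those that rose, had adjusted p = 0.13, oxidative phosphorylation genes 0.0737, plasma cell genes 0.198 and the 4 macrophage and monocyte markers 0.293. The 3 tested stromal cell markers had adjusted p = 0.196 after scaling and 0.00834 as deposited (adjusted p = 0.625 with an estimated correlation). Bgn had 0.0824 ± 0.0238 in TrB_WT and 2.58 ± 2.48 in eMZB_WT, and Acta2 1.43 ± 0.218 and 5.84 ± 7.64. Bgn reads were 33, 45 and 467 in eMZB_WT replicates 1, 2 and 3, and 66, 59 and 352 in those of eMZB_KO. Tagln reads were 22, 14 and 173, and 41, 26 and 56. Both genes were highest in replicate 3 of each eMZB group. Whether stromal cells were present there was not tested.

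In limma, 2693 genes passed between the wild-type cell types after scaling, 1440 higher and 1253 lower in eMZB, against 1896 as deposited, 1779 higher and 117 lower, with 1414 in both. The share of higher calls was 53.5% after scaling and 93.8% as deposited, so the balance of rises and falls rests on the scaling. Leaving out 1 library gave 1944 to 3407 after scaling.

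The same change was followed in knockout cells through the genes named in wild type. Marginal zone genes rose (13 of 15, 13 over the list alone; adjusted p = 4.8e-10), with Cr2 from 13.3 ± 1.79 in TrB_KO to 64.4 ± 1.32 in eMZB_KO, Dtx1 from 4.23 ± 1.14 to 41.3 ± 1.86 and Fcrl5 from 3.57 ± 0.782 to 32.7 ± 1.39. Transitional genes fell (9 of 9, also over the list alone; adjusted p = 2.6e-07), with Cd93 from 5.22 ± 0.782 to 0.831 ± 0.158 and Vpreb3 from 213 ± 18.8 to 77.0 ± 1.27. Il9r rose by 3.21 (SE 0.16) and Slc7a5 by 3.25 (SE 0.26), and Wfdc21 fell at -4.78 (SE 0.28). Flt3, chosen after its values were seen, rose from 0.433 ± 0.0339 to 5.15 ± 0.586, against 0.777 ± 0.0764 and 0.824 ± 0.207 in wild type.

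By camera, 9 of 22 lists were called in knockout, and the 6 that held with an estimated correlation were those that held in wild type. Cell cycle genes rose (25 of 26, 25 over the list alone; adjusted p = 2.0e-11), as did MYC and ribosome biogenesis genes (14 of 19, 15 over the list alone; 3.7e-09), glycolysis genes (12 of 15, 12 over the list alone; 3.9e-09) and heat shock genes (5 of 7, 5 over the list alone; 5.8e-05). B cell identity genes fell (10 of 16, 10 over the list alone; adjusted p = 1.6e-04, and adjusted p = 0.189 with an estimated correlation), with Spib from 225 ± 51.4 to 74.4 ± 3.73. Unfolded protein response genes rose (6 of 17, 7 over the list alone; adjusted p = 0.0075, and adjusted p = 0.492 with an estimated correlation), and so did oxidative phosphorylation genes (7 of 24, 8 over the list alone; adjusted p = 0.0438, and adjusted p = 0.504 with an estimated correlation). MHC class II genes, with 3 higher and 1 lower of 10, had adjusted p = 0.482; H2-Aa rose from 281 ± 17.6 to 418 ± 14.4. NF-kB pathway genes had adjusted p = 0.811, with a median below 0 and a mean above it. As deposited 11 lists were called, among them plasma cell genes, which fell (adjusted p = 0.0367, and adjusted p = 0.878 with an estimated correlation), and Notch pathway genes, which rose (0.0295, and adjusted p = 0.878 with an estimated correlation).

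In limma, 2695 genes passed between the knockout cell types after scaling, 1398 higher and 1297 lower in eMZB, against 460 as deposited, 387 higher and 73 lower, with 426 in both. The share of higher calls was 51.9% after scaling and 84.1% as deposited. Of the genes called after scaling, 1853 were called in the same direction in both genotypes and 2 in opposite directions, and the log2 changes of wild type and knockout correlated across all genes with Pearson r = 0.810 and Spearman rho = 0.787. Leaving out 1 library gave 1977 to 3082 after scaling.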

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

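Chosen after the result was seen were the test of a swap between wild-type and knockout libraries, the ratio of microRNA and snoRNA genes after scaling and the first of the tests on genes of families restricted to other tissues; the other tests below were set before their results were seen. Flt3 stood out because its response to LSD1 loss differed between the cell types in a test of that difference, by 1.94 on the log2 scale as deposited (limma interaction, adjusted p = 0.00698). Jchain stood out in the same test, at -4.17 as deposited (adjusted p = 0.00613), with reads that were uneven between replicates: 285, 1142 and 3802 in TrB_KO, 7, 454 and 367 in TrB_WT, 30, 154 and 234 in eMZB_KO, and 306, 197 and 777 in eMZB_WT.

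TrB_KO replicate 3 held 61.6% of its reads in the listed genes and 285 listed genes at 0. A few dominant genes are argued against by a share of the 10 highest genes at 0.714 times that of the highest other library, and background reads spread evenly over the genes of the other TrB libraries by an excess in genes of 2 to 5 scaled FPKM of 0.0631 of the level of genes at 0, and of -0.0755 in genes of 5 to 10. RNA of another cell type in it stays open, since 0% of the members of a marker list stood at least 2 times above the other TrB libraries, but 2 of the 8 lists had 3 or more listed members, and a gene high in this library alone would not be in the table. Reads from outside mature mRNA in the other TrB libraries, such as from genomic DNA, stay open and may account for part of the difference: microRNA and snoRNA genes, which such reads would make scarcer in TrB_KO replicate 3, lay at 1.52 times the others' mean as deposited and at 0.477 times after scaling, with 75 of 197 at 0 there against 25 to 40 in the others. Tests of families restricted to other tissues decide nothing either, the first with a ratio of 0 over 103 genes, 70 of them at 0 there, in families picked because they were at 0, and the second, in families picked without sight of the genes at 0, with 0.0892 over 7 genes (median 0.103 FPKM there), fewer than the 10 it asked for; no biological explanation was tested.

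Genes changed by LSD1 loss lay near each other: 23 of the 72 called in either cell type lay within 1 Mb of another called gene, against a median of 8 and a 95th percentile of 15 in 10000 random lists (one-sided permutation p = 2e-04), among them Ptprv, Rnpep and Csrp1 on chromosome 1, Srp54a, Fam177a and Srp54b on chromosome 12 and Rapgef3, Ddx23 and Arf3 on chromosome 15. Low reads are argued against for the 17 shared genes, with 0 of them under a mean of 20 reads in the higher group. The test did not cover the other genes of the 72, which include microRNA genes such as Mir1949 (mean of 6.33 reads) and Mir7211 (2.33). A chromosome segment that goes with the genotype, such as a strain-derived stretch, could give the 23. So could neighbouring genes that move together in any comparison, since 20 of as many top genes between the wild-type cell types also lay within 1 Mb of another. Pnrc2, called in eMZB and not among the 23, lies on chromosome 4 within 1 Mb of the targeted gene Kdm1a. For Pnrc2 a segment carried with the altered allele cannot be told apart from an effect of LSD1 loss. A copy number difference would move neighbours the same way, which the named genes on chromosomes 1 and 15 did not. In eMZB the log2 change was -0.86 for Rnpep, beside 1.05 for Ptprv and 0.73 for Csrp1. It was -0.79 for Arf3, beside 1.83 for Ddx23 and 0.81 for Rapgef3. Copy number stays open elsewhere, as for Srp54a (0.77), Fam177a (0.73) and Srp54b (0.74). Reads shared between near-identical copies stay open, with family copies within 1 Mb for 5 of the 17. Copies farther away were not looked for, so reads that Eno1b may share with Eno1 were not covered. A direct effect of LSD1 loss on these genes is a biological explanation that stays open and untested.

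Kdm1a was low in the libraries labelled TrB_WT replicate 3 and eMZB_WT replicate 3, at log2 differences of -1.05 and -0.67 from replicates 1 and 2. Length or level bias is argued against by 200 matched genes with a median of 0.0411, and a swap with the knockout library of the same number by Kdm1a there, within 0.0693 scaled FPKM of the mean of the other knockout libraries of its cell type. LSD1-deficient cells in the library labelled TrB_WT replicate 3 are argued against by its position of 1.07 on 37 genes called in the other cell type, where 0 is the knockout and 1 the wild-type level, while Kdm1a itself lay at 0.0961. For the library labelled eMZB_WT replicate 3 the position was 0.674 on 64 genes, with Kdm1a at 0.377, so LSD1-deficient cells may make up part of it and this cannot be told apart from spread between wild-type libraries. A difference in Kdm1a between wild-type animals stays open and untested.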

How the results depend on the processing

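Chosen after the data were seen were the alternatives on the scaled base, the fits without the libraries numbered 3, those without microRNA and snoRNA genes, the block in knockout libraries alone, and voom. Results are counts of called genes for LSD1 loss in TrB, LSD1 loss in eMZB, the wild-type cell type contrast, the knockout cell type contrast and the interaction, genes shared by both LSD1-loss contrasts, and called lists. As deposited these were 19, 15, 1896, 460, 15, 2 and 29. With a pseudocount of 0.1, TrB gave 10, eMZB 5 and the interaction 0. With a pseudocount of 5, TrB gave 12, eMZB 7, wild type 1123, the interaction 6 and the overlap 1. A filter at 5 FPKM, which left 5536 genes, gave 8 in TrB, 4 in eMZB, 214 in knockout and 2 in the interaction. Median-of-ratios scaling gave 49, 40, 2695 (knockout), 1 (interaction) and 17 (overlap), quantile scaling 46, 44, 2917 (wild type), 2664, 1 and 18, and TPM scaling 31, 33, 2555 (knockout), 1 and 14. Without trend, TrB gave 1, eMZB 4, knockout 273, the interaction 0 and the overlap 0. Library weights gave 9, 6196, 8876, 6304, 6 and 7. Fits on the compared libraries alone gave 130 in eMZB, 7511 in wild type and 129 in knockout. Without the libraries labelled WT replicate 3, TrB gave 29 and wild type 166, and without all 4 libraries numbered 3 TrB gave 29, eMZB 45, wild type 6266, knockout 5579 and the overlap 8. Without microRNA and snoRNA genes, TrB gave 9 and the interaction 3. An estimated correlation called 0 lists, down from 29. After scaling the counts were 49, 40, 2693, 2695, 1, 17 and 36. There the deposited scale gave 19, 15, 460 (knockout), 15 (interaction) and 2 (overlap), TPM 31 in TrB, the compared libraries alone 9, 65 (eMZB) and 6 (overlap), library weights 181 in eMZB and 18 in the interaction, and voom 21 in TrB. A log2 fold threshold of 1 gave 19, 13, 497, 408 and 5 (overlap). A pseudocount of 5 gave 6 in the interaction and the filter at 5 FPKM 0. Without the libraries labelled WT replicate 3 eMZB gave 23 and the interaction 2, and without all numbered 3 the interaction gave 3. An estimated correlation called 15 lists. A replicate block over all 12 libraries, as deposited, gave 49 in TrB, 28 in eMZB, 26 in the interaction and 5 shared genes; a block within cell type gave 47, 28, 28 and 4. After scaling the block within cell type gave 24, 13 and 7 (overlap). In the paired knockout contrast the block gave 636 over all libraries and 362 in knockout libraries as deposited, and 2674 and 2452 after scaling, and it moved no other count by over 1.5 times. Of the 12 libraries, 7 correlated best with a library of their own number. Leaving out 1 library gave, as deposited, 17 to 195, 13 to 42, 614 to 7459, 191 to 6688, 4 to 46, 2 to 8 and 29 to 34, and after scaling 26 to 54, 16 to 52, 1944 to 3407, 1977 to 3082, 1 to 5, 10 to 18 and 31 to 41. Where a fit dropped a library its group kept the others, and fits without the libraries numbered 3 had fewer residual degrees of freedom; for the other results that moved the cause was not tested. The test of the stromal cell marker list, called as deposited, turned direction in eMZB with library weights (adjusted p = 0.537), without eMZB_WT replicate 3 (0.0145), without the libraries labelled WT replicate 3 (0.0177) and without all numbered 3 (0.856), with 7.7e-12 to 0.166 over the fits leaving out 1 library, between the wild-type cell types with library weights (0.220), and between the knockout cell types with library weights (0.229) and without TrB_KO replicate 3 (0.714; 1.2e-04 to 0.714 over such fits). The log2 change of Btg2 in TrB turned to -0.46 with median-of-ratios and -0.51 with quantile scaling and, from the scaled base, to 0.157 as deposited, and Ptprc in eMZB to -0.178 with library weights. Among named genes, 4077 of the values as deposited and 4353 after scaling kept their side of the threshold, 40 and 34 of them with the opposite sign and not called, 110 and 199 lost the call and 236 and 44 gained it; among lists 1024 and 1063 kept their side, 1 and 3 with the opposite sign, 85 and 108 lost the call and 67 and 12 gained it. The fit with no filter could give no other value, since the filter removed no gene. Depth limits the microRNA and snoRNA genes, which had a median of 2 reads per library.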

Other observations

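The splits of scaled values, the overlaps of genes with the smallest p and the choice of genes in the paragraphs on biology here were made after the data were seen; the splits of deposited values were planned. Notch pathway genes, whose list did not pass after scaling, included members that rose from TrB to eMZB in both genotypes. Hes5, a direct Notch target, rose by 0.70 in wild type and 0.53 in knockout on the log2 scale, Dtx4 by 0.86 and 0.86, and Lfng, which modifies Notch receptors, by 0.55 and 0.77. Hes1, another target, had 9.52 ± 2.86 in TrB_WT and 7.33 ± 1.40 in eMZB_WT (limma adjusted p = 0.235). Follicular genes moved in both directions in both genotypes. Klf2, which restrains B cell activation and guides trafficking, fell at -1.48 in wild type and -1.70 in knockout, and the repressor gene Bach2 at -1.01 and -0.90, while the follicle homing receptor gene Cxcr5 rose by 0.80 and 0.72. These signs were the same as deposited, where Hes5, Dtx4, Lfng and Cxcr5 passed in wild type and Dtx4 in knockout. Fcer2a (CD23), a follicular marker, had 35.6 ± 3.45 and 33.3 ± 1.36 in wild type (adjusted p = 0.481) and fell in knockout from 43.7 ± 3.66 to 26.1 ± 0.613; the difference between genotypes did not pass (interaction -0.63, adjusted p = 0.17).

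Immediate early genes split by member between the cell types. Egr1, induced by B cell receptor signals, fell at -1.17 in wild type and -1.04 in knockout, while Egr3 rose by 0.74 and 0.30, Jun by 0.65 and 0.47 and Nr4a1 by 0.75 and 0.70, with the same signs as deposited, where Egr3, Jun and Nr4a1 passed in wild type and none of the 4 in knockout. Of the 11 tested LSD1 complex genes, 4 fell from TrB_KO to eMZB_KO, among them Kdm1b, the paralogue of Kdm1a, at -0.81, Hmg20b at -0.46 and Gse1 at -0.47, also with a negative sign as deposited, where these 3 did not pass. The list itself did not pass in knockout (adjusted p = 0.467) or in wild type (0.618), and neither did its interaction (0.518).

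Other splits of the same libraries were run for each count of calls. With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. As deposited, the real split gave 19 genes in TrB and the highest other 12, so 1 split reached 19; eMZB gave 15 and 18 (2 splits reached 15), the wild-type cell types 1896 and 10 (1 split) and the knockout cell types 460 and 6951 (3 splits). The splits with 4434 and 6951 calls joined TrB_KO replicates 1 and 2 with eMZB_KO replicate 1 or 2. They went with the scale of the deposited values, and both called 0 genes after scaling. The scale factors were 0.634 and 0.766 in TrB_KO replicates 1 and 2, and 1.17 and 1.10 in eMZB_KO replicates 1 and 2. The factors were 1.56 in eMZB_KO replicate 3 and 2.14 in TrB_KO replicate 3, which lay on the other side in both splits. With eMZB_KO replicate 3 in place of eMZB_KO replicate 1 or 2, 2 genes were called. The 4 other splits that parted 1 pair of knockout libraries of the same number, as those with 4434 and 6951 calls do, called 0 to 8. Neither setting TrB_KO replicate 3 apart nor keeping pairs together therefore gives such counts by itself. The 3 other splits that parted all 3 pairs, as the real one does, called at most 2. After scaling, TrB gave 49 and 2, eMZB 40 and 0, the wild-type cell types 2693 and 0, and the knockout cell types 2695 and 0, each reached by 1 split. Called lists after scaling numbered 3 in TrB with 5 as the highest other (3 splits), 9 and 9 in eMZB (2 splits), 10 and 12 in wild type (5 splits), and 9 and 8 in knockout (1 split).

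For the interaction, 100 splits within the cell types were drawn. As deposited, 7 of them gave at least the real 15 genes, the highest other 46, and after scaling 11 gave at least the real 1, the highest other 72. The split with 46 and 72 kept the real groups and swapped the genotype labels in 1 cell type. It turns a response shared by the cell types into an interaction, so its counts do not measure chance. Among the remaining splits the highest gave 25 as deposited and 6 after scaling, so chance was not excluded for the number of interaction genes. For the overlap of the called LSD1-loss genes, 2 of 100 splits shared at least the real 2 genes as deposited, the highest other 2. After scaling 1 split reached the real 17, the highest other 0, but 97 of the 99 other splits called no gene in one of the cell types, so their overlap had to be 0. Taking in every split as many genes with the smallest p as the real split called, 11 of 100 splits shared at least the real 2 as deposited, the highest other 3, so chance was not excluded there. After scaling, with 49 and 40 genes taken, 1 split reached the real 17, the highest other 2, so chance was excluded for this overlap among splits that ignore the pairing of the knockout libraries. Of all 28 splits that keep these pairs on the same side in both cell types, as the real one does, 2 shared at least the real 2 as deposited, the highest other 3, so chance was not excluded there, and after scaling 1 reached the real 17, the highest other 2, so it was excluded.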
